A study of Mus musculus with 13 samples.

How the data were processed

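Total liver RNA of 13 male mice was measured on Agilent 1-colour whole-mouse-genome arrays, with 1 mouse per array: 5 WT, 5 TAKI and 3 TEKI. Per the labels, the RNA was purified with a column kit and DNase, and 500 ng was labelled with Cy3. The scanner files were made with Agilent Feature Extraction 9.5, with spatial and multiplicative detrending switched on, per the file headers. The deposited values are the processed intensity of each spot, on a linear scale, with the background subtracted within the array and no scaling between arrays, per the file headers. The deposited value table held the same intensity values as the scanner files, with a largest absolute difference of 0, so it is on a linear scale, not centred and not scaled between arrays. Its column medians were 66.1, 72.9, 49.1, 64.8 and 58.0 for WT replicates 1 to 5, 70.1, 73.4, 72.6, 94.5 and 90.5 for TAKI replicates 1 to 5, and 137, 66.3 and 56.1 for TEKI replicates 1 to 3. It holds no differences between groups, so a direction of its values does not apply. How the tissue was taken, at what hour and in what order the samples were labelled is not given in the sources used here.

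Each array has 45018 spots, of which 43379 are not controls and carry 41174 probes, 245 of them on more than 1 spot. Spots of the same probe were averaged. Probes were named with the table of RefSeq accessions and symbols: 22951 by their accession, 6659 by the symbol in the file and 3109 by a synonym that belongs to 1 gene only, while 8455 kept the name in the file. This gave 27670 distinct names, 19505 of them current symbols. Intensities were taken to log2, and the 75th percentile of each array was subtracted. Per gene, the probe with the highest mean over the 13 arrays was tested, if the scanner software had marked it as well above background on at least 3 arrays, which left 20389 genes. No array was left out. Levels are log2 values relative to the 75th percentile of the array.

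Genes were tested with limma 3.58.1 in R 4.3.3, in 1 linear model of the 3 genotypes over all 13 arrays (10 residual degrees of freedom) with moderated t statistics, Benjamini-Hochberg adjustment over the genes of a contrast and a threshold of 0.05 on the adjusted p, for TAKI minus WT, TEKI minus WT and TEKI minus TAKI. A total of 31 lists of liver functions, of markers of other liver cells and of markers of neighbouring tissues, each with at least 5 members tested, went through camera with a preset correlation of 0.01 between genes, adjusted over the lists of a contrast. Counts of members adjusted over the list alone are given beside it. Confidence intervals of shares are exact binomial 95% intervals. The effects of both knock-ins were compared by correlation and covariance across genes. They were set against 100 simulated data sets of unchanged groups that shared 1 set of simulated WT arrays, drawn as independent noise. Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 read the files and drew the figures. Comparisons, tests, lists, alternatives and the rule for named genes were written before the data were examined.

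Named genes were chosen by rule. Among genes past the threshold, well above background and unsaturated on every array of both groups, with no overlap of the groups and with a current symbol, the 8 with the highest and the 8 with the lowest difference were named. Where fewer than 16 qualified, the genes of smallest p filled the places and are said not to pass. Up to 3 genes of smallest p that were well above background on every array of 1 group and on none of the other were named with a bound on the fold. From each list with a member past the threshold or with a shift, the 2 members of smallest p were named, and Sirt1 always. Other genes are said to be chosen after their values were seen. Some genes that the rule names are not reported here.

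The model was tested on simulated data with the real levels and spread of the 20389 genes. For TAKI minus WT, 7.46% of genes changed by 0.5 on the log2 scale were recovered, 65.7% of those changed by 1 and 84.8% of those changed by 2, with 1 false call. For TEKI minus WT these were 5.97%, 52.2% and 71.2%, with 3 false calls. The noise was drawn independently for each gene and array, so these false calls do not cover differences between slides, positions or single arrays. Spots of the same probe on an array had a median coefficient of variation of 3.5% to 6.6%, and the slope of the spike-in controls lay between 0.982 and 0.998. Correlations between arrays of a group were 0.976 to 0.991 in WT, 0.975 to 0.992 in TAKI and 0.965 to 0.983 in TEKI.

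The alternatives tried were other scalings and normalizations (median, quantile, normexp background correction with an offset of 50, the deposited table on its own scale), other filters on dim probes, the mean of all probes of a gene or every probe alone, an intensity trend, array weights, only the groups compared, slide as a random block and, for TEKI minus WT, as a fixed block or restricted to the slide that holds both, the scan day (2 days) as a block, the replicate number as a block, leaving out each replicate in turn, and for lists an estimated correlation and the rotation test fry. Alternatives chosen after seeing the data were a correction for the position on the array (a smooth surface with 6 degrees of freedom over the 532 rows and 4 over the 85 columns within 10 bins of level), only the brighter 0.5 of the genes with and without TEKI replicate 1, only genes with at least 2 probes above background, only probes in the middle of the rows, and TAKI minus WT without TEKI replicate 1. WT replicate 3 was the only array of its scan day, so the scan day block gives the same gene differences as leaving out that array. Tissue weights, blood values and protein data were not analysed here.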

Results

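Liver RNA was profiled from 13 male C57BL/6 mice kept for 5 months on a fatty diet of the western type. SIRT1 is an NAD-dependent protein deacetylase of energy metabolism, and its threonine 522 can be phosphorylated. The genotypes were 5 wild-type mice (WT), 5 knock-in mice with alanine in place of the threonine (TAKI), which cannot be phosphorylated there, and 3 knock-in mice with glutamate (TEKI), which carries a negative charge. The design text counts mice, and each array held the RNA of 1 mouse, so the replicates are separate animals. The comparisons ask how the 2 substitutions affect hepatic gene expression on this diet. Each animal was measured on 1 Agilent 1-colour whole-mouse-genome array of 45018 spots, and the spot intensities, background-subtracted by the authors' scanner software, were tested as log2 values relative to the 75th percentile of each array. The number of arrays limits the precision, most of all for TEKI.

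Sirt1 RNA did not differ past the threshold between the 3 genotypes. Its log2 level was 0.39 ± 0.12 (SD, n = 5) in WT, 0.38 ± 0.23 (SD, n = 5) in TAKI and 0.30 ± 0.25 (SD, n = 3) in TEKI, with a TAKI minus WT difference of -0.01 ± 0.13 (SE, adjusted p = 0.984) and a TEKI minus WT difference of -0.09 ± 0.15 (SE, adjusted p = 0.879). The other Sirt1 probe differed by 0.24 ± 0.12 (SE, unadjusted p = 0.0555 by limma) for TAKI minus WT and by -0.03 ± 0.13 (SE) for TEKI minus WT. For TEKI minus TAKI it differed by -0.27 ± 0.13 (SE, unadjusted p = 0.0647 by limma), so a small difference is not excluded. These probes measure the amount of transcript and do not test for the substitution, so they do not check the genotype labels.

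The share of probes well above background ranged from 60.5% to 73.1% on 12 arrays and was 86.8% on TEKI replicate 1. The same array had 87 spots marked as non-uniform, against 1 to 6 on each of the others. The arrays lay on 5 slides. WT replicates 1, 2 and 4 shared slide 1, WT replicate 3 was alone on slide 2, WT replicate 5 and all 3 TEKI replicates shared slide 3, TAKI replicates 1 and 2 shared slide 4, and TAKI replicates 3, 4 and 5 shared slide 5. No slide held TAKI together with another genotype, so slide and genotype cannot be told apart in comparisons with TAKI. Only WT replicate 5 was on a slide with TEKI.

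**Figure D1:**
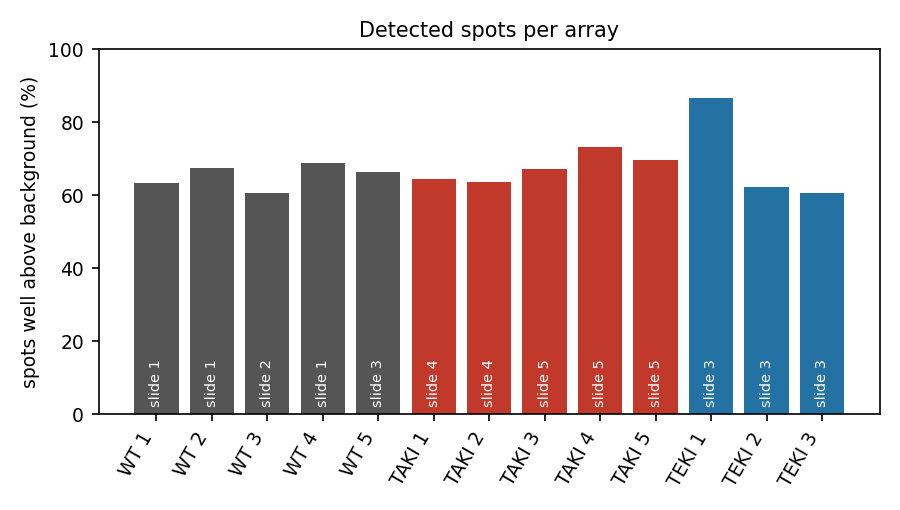
Share of spots well above background (%, vertical axis) on each of the 13 arrays, coloured by genotype, with the slide written in each bar. TEKI replicate 1 stood at 86.8%, and the other 12 arrays lay between 60.5% and 73.1%.

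In TAKI livers, 8 genes that rose and 8 that fell against WT were named by the rule. Ccdc189, a gene of motile cilia, rose 5.89-fold, from a log2 level of -1.86 ± 0.52 (SD, n = 5) in WT to 0.70 ± 0.17 (SD, n = 5) in TAKI (log2 difference 2.56 ± 0.23, SE, adjusted p = 0.00036). Omp, the olfactory marker protein of olfactory sensory neurons, rose 4.60-fold and the olfactory receptor Olfr406 rose 4.47-fold, with log2 differences of 2.20 and 2.16. Ntrk3, the receptor of neurotrophin-3, rose by 2.13 on the log2 scale, Spindoc by 2.03, Tgm3, a transglutaminase of the epidermis, by 1.95, Adam2, a protein of the sperm surface, by 1.93 and the adhesion receptor Adgrf3 by 1.79. Their adjusted p lay between 0.00036 and 0.0262. Scp2d1, which holds a sterol carrier domain, fell by 2.07 ± 0.33 (SE) on the log2 scale, and Pnmal1 by 1.90, Zc4h2, a neuronal zinc finger protein, by 1.86, the homeobox gene Nkx2-6 by 1.79, the somatostatin receptor Sstr4 by 1.69, Olfr398 by 1.53, Lypd6 by 1.49 and the prohormone convertase Pcsk2 by 1.48, with adjusted p from 0.0012 to 0.039. Among genes well above background on every TAKI array and on no WT array, Acrv1, a protein of the acrosome, was at least 2.08-fold higher in TAKI, Olfr401 at least 3.03-fold and Hhatl at least 2.60-fold (adjusted p = 0.00125, 0.00235 and 0.00255). Each bound sets the TAKI mean against the dimmest probes still well above background on the WT arrays. Olfactory receptor probes are open to cross-hybridisation between near-identical family members.

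In all, 570 of 20389 genes passed the threshold of limma with Benjamini-Hochberg adjustment, 379 higher and 191 lower in TAKI, and 2988 had an unadjusted p under 0.05. In 1525 genes (7.48%) the 5 TAKI values lay wholly above or below the 5 WT values, where random grouping gives 0.794%. The called genes were dim, with a median log2 level of -3.84 against -1.13 for all genes tested. Their place on the array followed their direction. Of the 379 called probes higher in TAKI, 371 lay in rows 1 to 266 of the 532 rows (97.9%, 95% exact interval 95.9 to 99.1), and of the 191 lower ones 5 did (2.62%, 0.855 to 6.00), while 50.4% of all tested probes did. Ccdc189 was in row 140, Ntrk3 in row 100 and Omp in row 56, and Scp2d1, Sstr4 and Pnmal1 were in rows 500, 523 and 506.

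**Figure D2:**
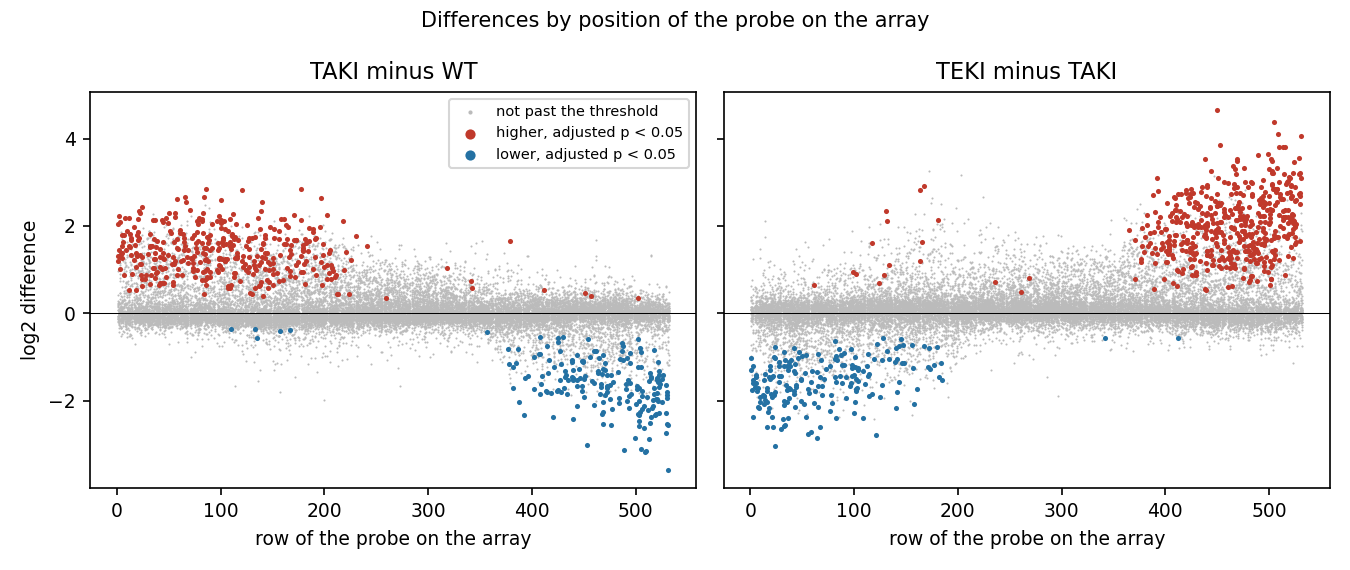
Log2 difference of each tested gene (vertical axis) against the row of its probe on the array (horizontal axis), for TAKI minus WT and TEKI minus TAKI. Red and blue points passed the threshold upward and downward, and grey points did not. Of the calls higher in TAKI than in WT, 97.9% lay in rows 1 to 266, and of the calls lower in TEKI than in TAKI, 99.0% did.

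Several called genes had another probe that did not move with the called one. Both probes lay in the same part of the rows for Ccdc189 (140 and 67), Scp2d1 (500 and 431) and Pnmal1 (506 and 354). They lay in different parts for Sstr4 (523 and 72) and Pcsk2 (446 and 101). The other Ccdc189 probe differed by -0.11 ± 0.19 (SE) and the other Scp2d1 probe by 0.27 ± 0.51 (SE). Other probes of Pnmal1, Sstr4 and Pcsk2 were higher in TAKI, by 1.21, 1.38 and 1.65 on the log2 scale, where the called probes were lower, and the mean of both Pcsk2 probes was 0.082 higher in TAKI. Over all called genes, 111 other probes of 92 genes were well above background, and 59 of them (53.2%, 95% exact interval 43.4 to 62.7) differed in the direction of the called probe. Their median difference in that direction was 0.07, against 1.11 for the called probes of those genes. Where both probes lay in the same part of the rows 33 of 52 (63.5%) had the same direction, and elsewhere 26 of 59 (44.1%, Fisher p = 0.0565).

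**Figure D3:**
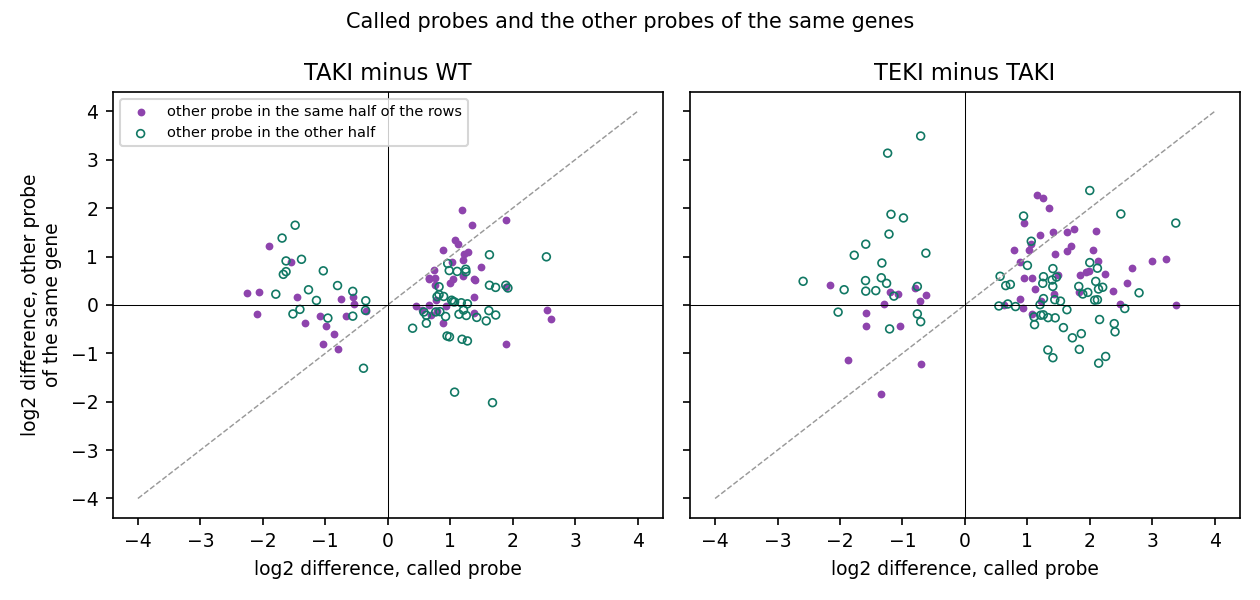
Log2 difference of another probe of the same gene (vertical axis) against that of the called probe (horizontal axis), with 1 point per other probe, filled where both probes lay in the same part of the rows (1 to 266 or 267 to 532) and open where they did not. The dashed line marks equal differences. In TAKI minus WT, 59 of 111 other probes had the direction of the called probe, and in TEKI minus TAKI 78 of 127 did.

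Of the 31 gene lists fixed for liver functions and cell types, 1 shifted in TAKI. Markers of T, B and NK lymphocytes rose against other genes by camera with a preset correlation, with a median log2 difference of 0.38 over 23 members and an adjusted p of 0.0028. The call was lost at an adjusted p = 0.988 with an estimated correlation. On single arrays the list stood at 0.42 ± 0.21 (SD, n = 5) in TAKI relative to the WT mean, where WT varied by 0.12 (SD, n = 5). Of its members 2 rose, 21 did not pass and 4 rose when adjusted over the list alone. Cd2, an adhesion receptor of T and NK cells, rose by 1.05 ± 0.14 (SE, adjusted p = 0.00315), from a probe in rows 1 to 266, and was higher in 5 of 5 TAKI animals than in any WT animal. In the list of pancreatic acinar markers 1 of 15 members rose and 2 fell, and the list did not shift (adjusted p = 0.752). Rnase1, the pancreatic ribonuclease, fell (adjusted p = 0.0208), as did Zg16, a protein of zymogen granules (adjusted p = 0.0311), with probes in rows 460 and 450. They were well above background on 3 and 1 of the 5 TAKI arrays, so no size of the difference is given. Adjusted over the list alone, 2 acinar markers rose and 2 fell. Of 10 skeletal muscle markers, Tnnc2, the troponin C of fast fibres, fell (adjusted p = 0.039, above background on 4 of 5 TAKI arrays), Myh1, a fast myosin heavy chain above background on 3 of 5 WT arrays, did not pass (adjusted p = 0.0971), and the list did not shift (adjusted p = 0.964). Adjusted over the list alone 1 muscle marker rose and 2 fell.

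The other 30 lists did not pass in TAKI, with adjusted p from 0.0521 to 0.964. Cholesterol synthesis and SREBP2 targets had 3 of 25 members above WT, with a median of -0.14 (adjusted p = 0.0521), and endothelial markers had 17 of 21 members above WT, with a median of 0.14 (adjusted p = 0.0521). Fatty acid oxidation and PPARalpha targets had a median of -0.02 (adjusted p = 0.766), fatty acid and triglyceride synthesis -0.12 (adjusted p = 0.273), gluconeogenesis and insulin response -0.08 (adjusted p = 0.766), oxidative phosphorylation -0.07 (adjusted p = 0.139) and NF-kappaB targets and chemokines 0.03 (adjusted p = 0.902), with no member passing in any of them. Of 18 cholangiocyte markers 2 rose when adjusted over the list alone (list adjusted p = 0.627). The count of 570 genes depended on the settings: 27 of 6769 genes passed when only genes with at least 2 probes above background were tested on the mean of those probes, and 1312 passed when TEKI replicate 1, which shares the estimate of the spread, was left out. With slide as a random block 439 genes passed.

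In TEKI livers, 1 gene passed against WT, where 98 passed without TEKI replicate 2 and 17 without WT replicate 5. Vmn1r19, a vomeronasal pheromone receptor, was well above background on all 3 TEKI arrays and on no WT array, and was at least 5.43-fold higher in TEKI (measured log2 levels -3.09 ± 0.84, SD, n = 3, and -7.60 ± 0.24, SD, n = 5, adjusted p = 0.000705). The dimmest TEKI value, -3.78, lay above the brightest WT value, -7.32. Its probe belongs to a family of near-identical receptors that is open to cross-hybridisation. The measured difference of 4.51, set against WT signal at background, was 4.42 with slide as a fixed block (adjusted p = 0.0538) and within slide 3 alone (adjusted p = 1.00), and fell to 1.11 with normexp background correction (adjusted p = 0.265) and to 0.98 with normexp and quantile normalization (adjusted p = 0.455). Over all settings its adjusted p ranged from 1.97e-05 to 1.00.

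None of the other named genes passed. Among those with the smallest p were Olfr1436 (log2 difference 0.79, adjusted p = 0.214), Olfr24 (1.18), the mesenchymal transcription factor Twist1 (1.13), Cd2 (0.85 ± 0.17, SE) and Olfr1350 (0.66), all but the first at an adjusted p of 0.227. Olfr32, Ranbp17, B4galt2, Calr4, Efcab1, Mmp17, Tnik, Mob3a and Tnfsf14 differed by 1.09, 1.12, 0.97, 0.91, 0.86, 0.82, 0.75, 0.59 and 0.58. Cep170b was the only one of these below WT, at -0.51 ± 0.11 (SE, adjusted p = 0.315). With slide as a fixed block Twist1 differed by 1.16, Cd2 by 1.15 and Cep170b by -0.47, with adjusted p of 0.618, 0.366 and 0.739, and Olfr1436 by 0.86. By limma 2385 genes had an unadjusted p under 0.05, and the groups did not overlap in 801 genes (3.93%), where random grouping gives 3.57%.

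By camera with the preset correlation, 8 lists shifted in TEKI relative to the other genes, whose median difference was 0.074. Each of the 8 had an adjusted p = 0.963 with an estimated correlation. Genes of the unfolded protein and integrated stress response fell together, with 24 of 26 members below WT and a median of -0.28 (adjusted p = 5.43e-06). The chaperone Hyou1 differed by -0.60 and Hsp90b1, the chaperone GRP94, by -0.34. Pancreatic acinar markers rose, with 14 of 15 members above WT and a median of 0.89 (adjusted p = 0.000836), among them Cel, the bile salt-stimulated lipase, at 0.91 and Prss2, a trypsinogen above background on 2 of 5 WT arrays, for which no size is given. Endothelial markers rose with a median of 0.26 (adjusted p = 0.0128), with Clec4g, a lectin of sinusoidal endothelium, at 0.45 and Esam at 0.43. Lymphocyte markers rose with a median of 0.42 (adjusted p = 0.0164), with Cd2 at 0.85 and Cd79a, a chain of the B cell receptor, at 1.42. Most acinar and lymphocyte markers were dim, with 2 of 15 and 4 of 23 among the brighter 0.5 of genes. Camera set them against all other genes, not against genes of like level. On TEKI replicate 1 dim probes rose in general, with a median excess of 1.77 in the dimmest of 4 equal groups of levels. The acinar markers had a median excess of 0.59 there. The 13711 tested genes in the same range of mean level, which is wide, had 0.25. Markers of macrophages and Kupffer cells (median -0.23), fibrosis and stellate cells (-0.18) and the NRF2 and glutathione genes (-0.11) fell at an adjusted p of 0.0128 each, and NF-kappaB targets and chemokines fell with a median of -0.16 (adjusted p = 0.0307). No member of the 8 lists passed over all genes, and adjusted over the list alone 2 lymphocyte markers rose and no member of the other 7 lists passed.

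The other 23 lists had adjusted p from 0.0771 to 0.975. Some named members went against their list. Clec4f, a Kupffer cell lectin, was 0.36 above WT, while Gpnmb, a glycoprotein of lipid-laden macrophages, was at -2.07 ± 1.12 (SE). Cxcl9, an interferon-induced chemokine, was 0.79 above WT and Nfkb1 at -0.29. Gsta3, whose probe is open to cross-hybridisation with other glutathione transferases, was at 0.27 and Txnrd1, thioredoxin reductase, at -0.34. Des, the muscle and stellate cell filament, was at 0.35 and Pdgfrb, a receptor of stellate cells, at -0.40. With median scaling Gsta3, Des, Clec4f and Esam stood at -0.16, -0.085, -0.072 and -0.0013. That scaling shifts all genes of a contrast alike, and these genes stayed above the median of all genes, -0.36. With slide as a fixed block Gsta3, Nfkb1 and Pdgfrb turned, to -0.16, 0.028 and 0.28, and Hyou1, Clec4g, Cel and Cxcl9 stood at -0.29, 0.07, 0.35 and 1.14. The lists moved unevenly over the 3 TEKI arrays. Acinar markers stood at 1.46, 0.33 and 0.84 relative to the WT mean on TEKI replicates 1, 2 and 3, lymphocyte markers at 1.20, 0.43 and -0.17, and macrophage markers at 0.13, 0.28 and -1.25. TEKI replicate 1, with 86.8% of probes above background, had the highest acinar and lymphocyte values.

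**Figure D4:**
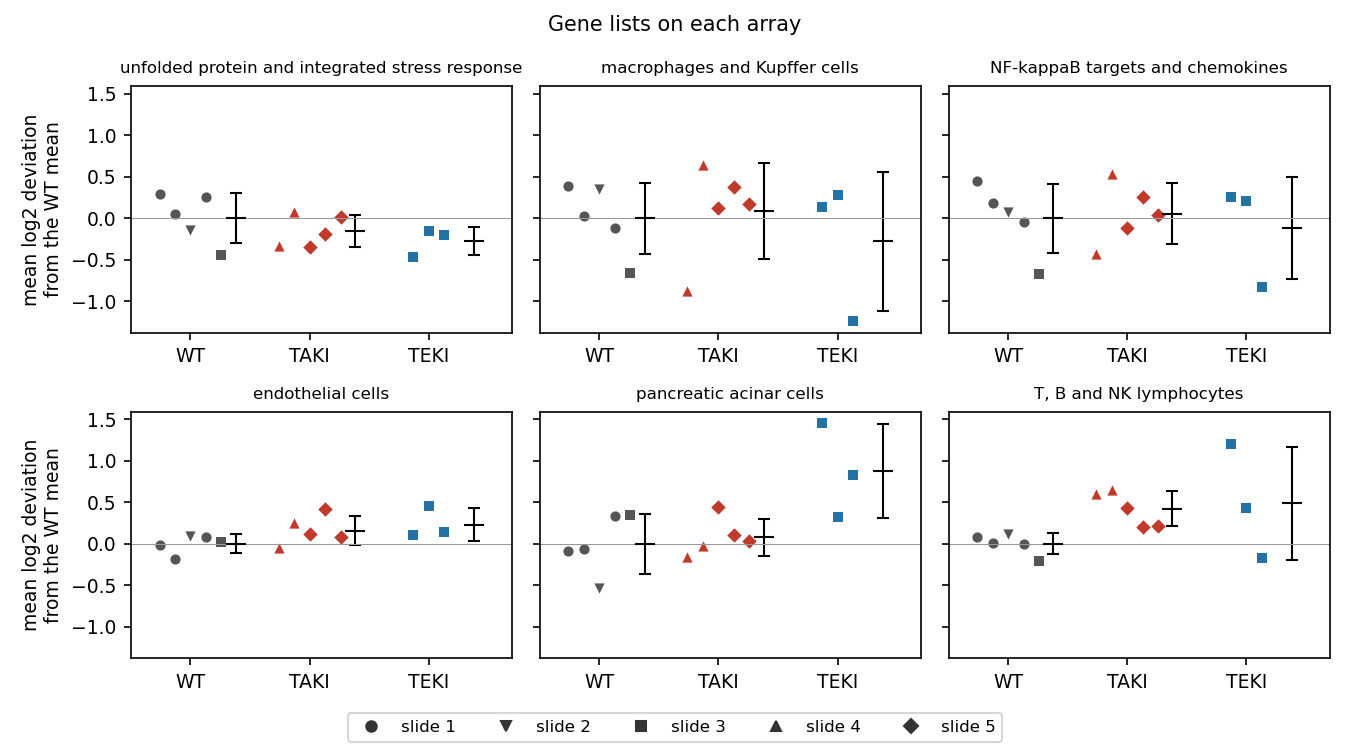
Mean log2 deviation from the WT mean (vertical axis) of the members of 6 gene lists on each of the 13 arrays, by genotype, with the slide shown by the marker. Bars give the mean ± SD of each genotype (n = 5, 5 and 3). In TEKI, acinar markers stood at 0.87 ± 0.57 and macrophage markers at -0.28 ± 0.84, and WT replicate 5, on the slide of the TEKI arrays, had the lowest macrophage value of the WT arrays.

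On slide 3 TEKI could be compared with WT replicate 5 alone. The values with slide as a block rest on that single WT array and on the preset correlation, so they set no direction. With slide as a fixed block the mean difference was 0.55 for NF-kappaB targets (adjusted p = 0.00481), 0.39 for macrophage markers (adjusted p = 0.128), 0.29 for fibrosis markers (adjusted p = 0.112), 0.17 for the unfolded protein response (adjusted p = 0.701) and 0.13 for the NRF2 genes (adjusted p = 0.652). The mean differences were the same within slide 3 alone. Lymphocyte markers stood at 0.69 (adjusted p = 0.000486), endothelial markers at 0.21 (0.0655) and acinar markers at 0.53 (0.112). With each array scaled to its median, which moved the median of all genes in TEKI minus WT to -0.36, the mean of the endothelial list was -0.20 and the list did not pass (adjusted p = 0.702). Without TEKI replicate 1, 5 of the 8 lists passed in the same direction, and lymphocyte, NRF2 and fibrosis lists had adjusted p of 0.513, 0.277 and 0.418. The mean moved from 0.49 to 0.13 for lymphocyte, 0.87 to 0.58 for acinar and 0.23 to 0.30 for endothelial markers. It moved from -0.28 to -0.49 for macrophage markers, -0.12 to -0.31 for NF-kappaB targets and -0.28 to -0.18 for the unfolded protein response. For fibrosis markers it went from -0.18 to -0.13, and for NRF2 genes it stayed at -0.12. Without TEKI replicate 3 the mean of NF-kappaB targets was 0.24 and that of macrophage markers 0.21, and neither passed.

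The glutamate and alanine knock-ins differed from each other in 699 genes by limma, 505 higher and 194 lower in TEKI, with 2468 genes at an unadjusted p under 0.05. Without TEKI replicate 1 the balance turned, with 379 higher and 722 lower. Myh2, a fast myosin heavy chain, rose 10.4-fold from TAKI to TEKI, from -3.17 ± 0.93 (SD, n = 5) to 0.20 ± 0.79 (SD, n = 3), with an adjusted p of 0.0198. Olfr218 rose by 2.76 on the log2 scale, Scp2d1 by 2.68, Zc4h2 by 2.52, Nkx2-6 by 2.50, Pnmal1 by 2.48, the secreted C1q-related protein C1qtnf4 by 2.40 and Rnf151, a ring finger protein of sperm, by 2.36, with adjusted p between 0.00206 and 0.0308. Olfr128 fell by 2.86, Ntrk3 by 2.27, Ccdc189 by 2.16, Olfr845 by 2.15, Olfr382 by 2.02, the LIM protein Fhl3 by 1.93, Spindoc by 1.91 and Tcl1b2 by 1.89, with adjusted p between 0.000634 and 0.0125. Genes well above background on every TEKI array and on no TAKI array included Vmn1r19, at least 5.77-fold higher in TEKI, Odf3l1, at least 4.86-fold, and Olfr1044, at least 3.38-fold (adjusted p = 0.000248, 0.00124 and 0.000634). No slide held both knock-ins. On WT replicate 5, from the slide of TEKI, Myh2 was at 0.56, where the other WT arrays lay between -2.49 and -0.79. C1qtnf4 was at 0.95 there and Olfr128 at -1.66, and all of these values lay within the TEKI range. Olfr382 and Fhl3, at -1.94 and -2.50 on that array, lay above every TEKI value.

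Here too the direction followed the place of the probe. Of the 505 probes higher in TEKI 16 lay in rows 1 to 266 (3.17%, 95% exact interval 1.82 to 5.09), and of the 194 lower ones 192 did (99.0%, 96.3 to 99.9). Other probes of the called genes had the direction of the called probe in 78 of 127 cases (61.4%, 52.4 to 69.9), in 43 of 53 (81.1%) where both probes lay in the same part of the rows and in 35 of 74 (47.3%) where they did not (Fisher p = 0.000107). Other Myh2 probes differed by 0.0036 and 1.69, another Fhl3 probe by 0.31 against -1.93, and another C1qtnf4 probe by -0.56 against 2.40, while another Nkx2-6 probe differed by 1.88 in the same direction as the called one. The groups did not overlap in 1695 genes (8.31%, with 3.57% from random grouping). With normexp background correction 4203 genes passed, and in the 6769 genes with at least 2 probes above background 53 did.

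Markers of macrophages and Kupffer cells fell from TAKI to TEKI by camera, with 22 of 26 members lower, a median of -0.32 and an adjusted p of 0.0426, and with an adjusted p = 0.990 with an estimated correlation. No member passed, and none did adjusted over the list alone. Adgre1, the F4/80 antigen, differed by -0.55 ± 0.43 (SE), and Mmp12, macrophage elastase, was above background on 2 of 3 TEKI arrays (adjusted p = 0.639). Without TEKI replicate 3, whose macrophage value was the lowest of all 13 arrays, the mean of the list was 0.12 and it did not pass. Among the sirtuins and NAD metabolism genes 1 of 24 members rose, also when adjusted over the list alone. Sirt6, a chromatin deacetylase, rose (adjusted p = 0.00843). Its probe in row 480 was above background on 4 of 5 TAKI arrays, so no size of the difference is given. Sirt3, the main mitochondrial deacetylase, was 0.34 higher without passing, and the list did not shift (adjusted p = 0.784). Of the acinar markers 2 rose, Rnase1 (adjusted p = 0.00546) and Zg16 (adjusted p = 0.00796), again with probes above background on 3 and 1 of the 5 TAKI arrays, and 3 did when adjusted over the list alone, and of the skeletal muscle markers Myh2 rose by 3.38 and Tnnc2, above background on 4 of 5 TAKI arrays, rose as well (adjusted p = 0.00891), while neither list shifted (adjusted p = 0.0633 and 0.325). Adjusted over the list alone 2 muscle markers rose and 1 fell. Cholesterol synthesis and SREBP2 targets were higher in TEKI in 25 of 25 members, with a median of 0.27, and the list did not pass (adjusted p = 0.0601). Oxidative phosphorylation genes had 41 of 45 members higher, with a median of 0.14 (adjusted p = 0.0633). Adjusted over the list alone, 1 of 14 neutrophil markers rose, and the list did not shift (adjusted p = 0.427).

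The effects of both substitutions were set side by side over the 20389 genes. The log2 differences of TAKI and TEKI from WT correlated at r = 0.284 across genes, which are not independent replicates. Both comparisons share the WT arrays, and unchanged groups simulated against the same arrays gave r = 0.434. The covariance was 0.068, against 0.0472 in the simulation. With the WT arrays split so that each knock-in had its own controls, r had a median of 0.112 over 10 splits (0.0476 to 0.148). No gene was called in both knock-ins. Independent lists of the higher calls alone give 0.0186 genes higher in both. With so few to be found by chance, the lack of shared calls does not show whether the effects are shared. Of the 571 genes called in either knock-in, 348 passed the direct test of TEKI against TAKI, and 347 genes were called both in TAKI minus WT and in TEKI minus TAKI, all with opposite sign. Both of those contrasts hold the TAKI arrays, with opposite sign, which alone makes them share such calls. Ccdc189, Ntrk3 and Spindoc were among those higher in TAKI than in both other genotypes, and Scp2d1, Zc4h2, Nkx2-6 and Pnmal1 among those lower.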

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

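The 8 values below were each found by the same rule, which asks in every group of 5 arrays whether the highest or lowest value is far from the other 4 relative to the range of the group. It was applied to 156 groups of values, and chance alone gives about 1 in 20. No test of these values was chosen after they were seen, and no biological explanation was tested.

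WT replicate 5, the only WT array on the slide of the TEKI arrays, held 3 of them: Mob3a at -2.14 (the other WT arrays -2.61 to -2.57), Olfr128 at -1.66 (the others -0.04 to 0.42) and Pdgfrb at 0.72 (the others 1.52 to 1.63). Efcab1 was at -4.79 in WT replicate 3, where the others lay between -4.20 and -4.02, and Olfr1436 at -4.43 in WT replicate 4, where the others lay between -4.69 and -4.66. WT replicate 1 had 35 saturated spots against 24 to 27 on the others. In TAKI replicate 3, Ccdc189 stood at 1.00 (the others 0.57 to 0.67), and that array had 1 non-uniform spot where each of the other TAKI arrays had 2.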

How the results depend on the processing

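Among the named genes past the threshold in TAKI minus WT, 583 results of single alternatives kept direction and call, 81 kept the direction without passing and 2 turned. In TEKI minus TAKI 536 kept both and 33 kept the direction. Most of these alternatives used the same probe of each gene again, so they are not independent checks. With the mean of at least 2 probes, 1 result of TAKI minus WT kept both, 5 kept the direction and 1 turned. In TEKI minus TAKI 2 kept both and 6 kept the direction by that mean. The lymphocyte list of TAKI minus WT kept its call in 24 alternatives and lost it in 5, the macrophage list of TEKI minus TAKI kept it in 17, lost it in 10 and turned in 1, and the lists of TEKI minus WT kept it in 145, lost it in 78 and turned in 12. Most calls were dim: the called genes of TAKI minus WT had a median level of -3.84 against -1.13 for all genes, and 44 of 570 were among the brighter 0.5 of genes. Except where a sentence names fewer genes or arrays, the cause of a difference was not tested. Tests chosen after the data were seen were the position correction, the brighter genes, at least 2 probes, the middle rows and leaving TEKI replicate 1 out of TAKI minus WT.

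For TAKI minus WT the count of 570 genes (379 higher, 191 lower) became 994 (576, 418) with median scaling, 872 (523, 349) with quantile normalization, 875 (537, 338) with normexp and quantile normalization, 631 (163, 468) with normexp and the 75th percentile, 1008 (851, 157) with the authors' table on its own scale, 375 with the mean of all probes, 2305 with array weights and 1333 with only the 2 groups compared. Of the alternatives chosen after seeing the data, the spatial correction gave 295 (266 shared), the brighter genes 20, the same without TEKI replicate 1 25, TEKI replicate 1 left out 1312, at least 2 probes 27 and the middle rows 70. Of these, the brighter genes (10194), at least 2 probes (6769 genes) and the middle rows (10607) test fewer genes. Leaving out each replicate gave 283 to 613. The median difference of all genes moved to -0.15 with median scaling and to 0.22 on the own scale.

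For TEKI minus WT the 1 gene became 2 with median scaling, no filter or array weights, 5 with quantile normalization, 8 with slide as a fixed block, and 0 with both normexp settings (unadjusted p under 0.05 by limma in 3470 and 2024 genes), within slide 3 (446), in the brighter genes (530), in the same without TEKI replicate 1 (310), with at least 2 probes (658) and in the middle rows (1431). Leaving out each replicate gave 1 to 98. The median difference of all genes moved to -0.36 with median scaling. For TEKI minus TAKI the 699 genes (505 higher, 194 lower) became 1116 (488, 628) with quantile normalization, 4203 (4034, 169) with normexp and the 75th percentile, 1134 (524, 610) with normexp and quantile normalization, 368 with the spatial correction, 29 in the brighter genes, 3 in the same without TEKI replicate 1, 53 with at least 2 probes and 14 in the middle rows, with splits of 517 and 500 for median scaling (1017) and 343 and 256 on the own scale (599). The median difference moved to -0.21 with median scaling and on the own scale, and leaving out each replicate gave 408 to 1101 genes (379 higher and 722 lower without TEKI replicate 1).

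The 1 list of TAKI minus WT became 2 with quantile normalization, normexp and quantile normalization, no filter or scan day, 4 with normexp and the 75th percentile or the middle rows, 3 with an intensity trend, and 0 on the own scale, with array weights, an estimated correlation or fry, and leaving out each replicate gave 1 to 7. The 8 lists of TEKI minus WT became 3 with median scaling, quantile normalization or normexp and quantile normalization, 13 with normexp and the 75th percentile, 18 within slide 3, 4 with scan day, 0 with an estimated correlation or fry, 5 in the brighter genes or the middle rows and 1 with at least 2 probes, and leaving out each replicate gave 4 to 10. The 1 list of TEKI minus TAKI became 14 with normexp and the 75th percentile, 9 without a filter, 3 with genes above background on every array of a group, 2 with the mean of all probes or the middle rows, 7 with an intensity trend, 4 with array weights, 5 in the brighter genes, 6 in the same without TEKI replicate 1, and 0 with slide as a random block (consensus correlation 0.0426), at least 2 probes, an estimated correlation or fry. Leaving out each replicate gave 0 to 8. Adjusted p of the lymphocyte list in TAKI minus WT ranged over the settings from 0.000123 to 0.988, that of the macrophage list in TEKI minus TAKI from 5.07e-06 to 0.990, and that of the endothelial list in TEKI minus WT up to 0.963.

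The direct test of TEKI against TAKI for genes called in either knock-in gave 723 with median scaling, 682 with quantile normalization, 562 and 702 with normexp, 729 with array weights, 130 with the spatial correction, 11 in the brighter genes, 2 in the same without TEKI replicate 1, 14 with at least 2 probes and 9 in the middle rows, against 348, and 181 to 891 when leaving out each replicate. The correlation of both knock-in effects, 0.284, became 0.167 with quantile normalization, -0.0957 with normexp and the 75th percentile, 0.134 without a filter, 0.112 with the WT arrays split, 0.361 with the spatial correction, 0.386 in the brighter genes, and 0.125 to 0.386 when leaving out each replicate.

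Directions that turned were, in TEKI minus WT with median scaling, Gsta3 (-0.16), Des (-0.085), Clec4f (-0.072) and Esam (-0.0013), and with quantile normalization Olfr1436 (-0.017). The turns with median scaling reflect a shift of all genes alike, to a median of -0.36. The slide as a fixed block, or slide 3 alone, turned Gsta3 (-0.16), Nfkb1 (0.028), Pdgfrb (0.28) and the lists of NF-kappaB targets (0.55), the unfolded protein response (0.17), NRF2 (0.13), fibrosis (0.29) and macrophages (0.39). Leaving out each replicate gave -0.31 to 0.24 for NF-kappaB targets and -0.56 to 0.21 for macrophages in TEKI minus WT, and -0.64 to 0.12 for macrophages in TEKI minus TAKI. Pcsk2 in TAKI minus WT stood at 0.082 with the mean of all probes or at least 2 probes. Sirt1, TAKI minus WT, stood at 0.21 on the own scale, 0.12 with the mean of all probes or at least 2 probes, 0.00048 with scan day and 0.036 with the spatial correction. Without each replicate Sirt1, TAKI minus WT, lay between -0.084 and 0.054, Sirt1, TEKI minus WT, between -0.18 and 0.058, and Sirt1, TEKI minus TAKI, between -0.17 and 0.069.

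Replicate numbers are shared by the groups, and the labels give them no meaning. Deviations of arrays with the same number correlated between -0.23 and 0.32, and only TEKI and TAKI replicate 2 correlated best with each other. With the replicate block 324 genes passed in TAKI minus WT, 1 in TEKI minus WT and 599 in TEKI minus TAKI, with 1, 8 and 9 lists, 205 genes in the direct test and a correlation of both effects of 0.258. The arrays share only a number.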

Other observations

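Apart from the genotypes, single animals differed from each other in known liver programs, and the genes named here were chosen after their values were seen. Hsd3b5, a male-specific steroid dehydrogenase, varied most among 12803 named genes that were well above background and unsaturated on every array, from -5.50 in WT replicate 2 to 3.25 in TAKI replicate 1 (SD within groups 3.28, against a median of 0.207). The male-biased liver genes as a list were lowest in WT replicate 2 (-0.83) and TAKI replicate 4 (-0.79) and highest in TEKI replicate 3 (0.89) and TAKI replicate 1 (0.84). WT replicate 1 had the highest acute phase genes of all arrays (list mean 1.02), with Saa3 at 8.66 and Lcn2 at 5.45, where WT replicate 5 had 3.34 and -1.01, and the scavenger receptor Marco at 5.63. The same animal had the lowest clock output genes (list mean -0.64), with Ciart at -4.19 and Usp2 at -2.35, where WT replicate 5 had 0.11 and 2.35. The median within-group SD was 0.689 for neutrophil markers, 0.623 for macrophage markers, 0.590 for acute phase proteins and 0.560 for clock genes, against 0.150 for oxidative phosphorylation.

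In TAKI minus WT, 13 called genes lay in the part of the array where calls of the other direction were found, and they too are named after their values were seen. In rows 1 to 266, 5 were lower in TAKI: the RNA-binding protein Celf2 (-0.56, adjusted p = 0.0146), Cep170b (-0.40), Actr5 (-0.39), Mbtps1, the site-1 protease that activates SREBP and ATF6 (-0.36, adjusted p = 0.0487), and the ubiquitin ligase Nedd4 (-0.35). In rows 267 to 532, 8 were higher, among them the glycosyltransferase Mgat2 (0.35), the RAS exchange factor Sos1 (0.40), Etaa1 (0.46), Cep44 (0.53), Rab10os (0.59) and Calr4 (0.73). All but Celf2 and Rab10os (adjusted p = 0.0169) had an adjusted p between 0.0326 and 0.0499 by limma. At a threshold of 0.05 some of the 570 calls are false, and these 13 may be among them. Other probes of these genes went either way. Against the called probe went -0.48 for Sos1, 0.09 for Nedd4, and 0.17 and 0.28 for Celf2. Its direction was shared by -0.23 for Celf2, -0.12 and -0.11 for Mbtps1, and -1.31 for Actr5. After the spatial correction 3 of the 13 passed: Cep44 (0.90, adjusted p = 0.00139), Rab10os (0.71, adjusted p = 0.0146) and Etaa1 (0.49, adjusted p = 0.0497).

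The tests of probe position, of other probes and of why TEKI replicate 1 stands apart were chosen only after the results were seen. The fits with slide and without TEKI replicate 1 were planned but set against these patterns afterwards, and the splits and the test of Sirt1 neighbours were chosen beforehand.

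The first pattern is the calls of TAKI minus WT and of TEKI minus TAKI, for whose number chance is excluded: 1 of 100 splits of the WT and TAKI arrays reached 570 genes, the real one, and the highest other gave 20, and for TEKI minus TAKI 1 of 56 reached 699, with 2 as the highest other. The direction of the calls followed probe position. In rows 1 to 266 lay 97.9% of the calls higher in TAKI than in WT and 99.0% of those higher in TAKI than in TEKI. Of the opposite calls 2.62% and 3.17% lay there, against 50.4% of all tested probes. These shares go with an effect of probe position on the direction. The spatial correction left 295 and 368 genes and lowered the median absolute difference of the calls from 1.46 to 1.12 (median SE 0.26 and 0.25) and from 1.81 to 1.36 (median SE 0.32 and 0.31), and of the TAKI minus WT calls left, 89.5% of the higher and 10.6% of the lower still lay in rows 1 to 266. A change of the transcripts could be checked only in called genes with another probe above background, 92 of 570 and 111 of 699. Other probes had the same direction in 53.2% (TAKI minus WT) and 61.4% (TEKI minus TAKI). Where both probes lay in the same part of the rows 63.5% and 81.1% did, and 44.1% and 47.3% elsewhere. The other probes were the dimmer ones, and of those within 1 log2 of the called probe 52.8% and 64.4% shared its direction. These shares argue against a change of the transcripts as the whole cause in those genes. The remaining calls were not tested in this way. Genotype and slide could not be told apart: 439 genes passed with slide as a random block, and no slide held TAKI with another genotype.

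The next pattern is TEKI replicate 1, where 4516 of 8843 probes (51.1%) that were not well above background on the other 12 arrays were so. An effect of the TEKI alleles is excluded, since TEKI replicates 2 and 3 had at most 62.3% of probes above background. A raised optical background stays open: the raw mean of its negative controls, 69.7, lay within those of the other arrays, while its median local background, 90, was the highest, with 50 to 81.5 on the others. The median excess of these 8843 probes over TEKI replicates 2 and 3 was 1.82 on the log2 scale. They were chosen for low signal on arrays that include TEKI replicates 2 and 3, which alone raises the excess. So this value cannot by itself exclude RNA of a neighbouring tissue as the whole cause. By mean level the excess was 1.77, 1.45, 0.17 and -0.10 from the dimmest to the brightest of 4 equal groups, so the rise of dim probes was broad. Its origin was not found.

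The last pattern is the shift of 8 lists in TEKI minus WT, for which chance cannot be excluded: 48 of 56 splits of these arrays called at least 8 lists, with 20 as the highest other, so the camera calls with a preset correlation may reflect structure among the arrays. For the lists of TAKI minus WT and TEKI minus TAKI, 100 of 100 and 56 of 56 splits called at least as many, with up to 21 and 18. For genes in TEKI minus WT, 13 of 56 splits reached the real count of 1, and the highest, 479, set WT replicate 5 with TEKI replicates 1 and 3, against the rest, which points to a structure of the samples. These 3 arrays are all from slide 3, as is TEKI replicate 2 in the rest. Whether TEKI replicate 1 caused the shifts cannot be told apart: 5 of the 8 passed without it, by a measure that most splits also pass.

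A passenger segment around the edited gene was tested as a hypothesis on the nearest 40 tested neighbours of Sirt1, and stays open. None was called in either knock-in, with an upper 95% limit of 8.81%, and 2 had an unadjusted p under 0.05 by limma in each (Fisher p = 0.630 and 1, smallest adjusted p 0.233 and 0.386). With 570 and 1 calls among the 20349 other genes, about as few were to be found by chance, so the limit set beforehand was too wide to exclude it.

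The first principal component held 33.9% of the variance and the next 19.0%. TEKI replicate 1 stood at 136 on the first, where the other arrays lay between -66.4 and 19.0. On the next, TAKI arrays lay between -50.4 and -21.0, WT between 13.1 and 55.5 and TEKI between -4.39 and 47.3. TAKI shared no slide with the others. Pairs of probes of the same gene, both among the brighter 0.5 of genes, were compared by their deviations from the group means. These deviations had a median correlation of 0.70 over arrays (2675 pairs), and 0.94 in the 268 pairs of widest spread. Most calls were dimmer, with 44 of the 570 of TAKI minus WT among the brighter genes.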
